A study of Mus musculus with 3 samples.

How the data were processed

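Single-cell RNA was measured with Chromium Single Cell 3′ v3.1 chemistry in 3 mouse libraries, with 1 library in each group. Per the labels, the chimera cauda library came from a Tsc22d3-knockout chimera that had been complemented with induced pluripotent stem cells (iPSCs) of mouse, of the line Pax7-nGFP iPS x goGermline. The KO cauda library came from a Tsc22d3 knockout of the goGermline line, whose males are sterile and serve as hosts for donor germ cells. Both were aspirated through the skin from the cauda epididymis, the tail of the duct in which sperm are stored. The KO testis library came from the testis of an adult knockout, dissociated by a published protocol for testicular cells. Samples were grouped by their titles.

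The deposited matrices hold raw UMI counts (unique molecular identifiers, 1 per captured transcript molecule) per gene and barcode, as whole numbers with no normalization, for the same 26124 genes in all 3 libraries. The submitters' processing notes name Cell Ranger 6, Seurat 4.2.1 and the mouse build GRCm38.p6. Per the file headers, the chimera matrix was written by Cell Ranger 4 and both KO matrices by Cell Ranger 6.1.2, so the software version is confounded with chimera against KO. The matrices also differ in how far they were filtered. The chimera matrix holds 214502 barcodes with at least 1 UMI and 86665 with 0 UMIs, and 222 of its barcodes reach 500. In the KO cauda and KO testis matrices the lowest barcode holds 501 and 500 UMIs. The comparison of the cauda libraries is therefore given over all barcodes, as fixed in advance, and for the gene counts, the gene lists and the main marker sets again over barcodes with at least 500 UMIs, where the libraries share a lowest UMI count. Whether their barcodes were otherwise chosen alike is not known. Positions come from the GENCODE M21 annotation of GRCm38, in which 26013 of the 26124 gene IDs (99.6%) were found. A total of 73 genes carry a symbol that another gene also carries, and a list member with such a symbol was taken from its first occurrence.

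The total was 5395856 UMIs for the chimera cauda, 41862286 for the KO cauda and 134795047 for the KO testis. Values are CPM, the UMIs of a gene scaled to the total of its library or class. A count of 0 allows up to 3 UMIs, which is 0.556 CPM in the chimera cauda, 0.0717 CPM in the KO cauda and 0.0223 CPM in the KO testis, and a fold against 0 was taken against this floor as a lower bound. Levels carry exact Poisson 95% intervals, shares exact (Clopper-Pearson) binomial 95% intervals, and folds exact conditional binomial 95% intervals. With 1 library per group there is no spread between animals, so no test of the conditions was run. All intervals and floors cover counting error only.

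The design of the comparisons, the gene lists and the alternatives were fixed before the data were examined. For library sums, a gene was past the size rule when it differed by at least 4-fold and reached at least 100 CPM in the higher library. The genes named in each direction were the 12 with the largest fold among those with at least 100 CPM, or the 10 largest for a cell class, leaving out mitochondrially encoded genes, ribosomal protein genes, and gene models named Gm plus digits or ending in Rik. Members of a fixed list were named as examples when they were among the 4 with most UMIs. Any other gene named was chosen after its values were seen. The 17 fixed lists were sperm chromatin compaction, sperm flagellum, acrosome and egg binding, sperm energy metabolism, sperm ion transport, meiosis, pan-germline genes, Sertoli secretion and nursing, steroidogenesis, epididymal secretion, proton secretion, early stress response, interferon response, MHC class II, inflammatory cytokines, glucocorticoid response and cell cycle, beside marker sets of 25 cell types. A list was summarised by the median log2 ratio of its measured members, those with more than 3 UMIs in either library, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists of the same size matched in 20 bins of mean expression. A member with 0 UMIs stood at the floor. The floor of the shallow chimera library lies above low levels of the KO cauda, so the medians of sparse lists lean upward, more so with at least 500 UMIs, and the number of members whose own interval excludes a ratio of 1 is given beside most of them.

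Barcodes kept as cells had at least 500 UMIs and 200 genes and at most 20% mitochondrially encoded UMIs. Doublets were scored by the share of simulated doublets, 2 per cell, among each cell's nearest neighbours, and the highest 0.8% per 1000 cells were removed. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were grouped on a graph of 15 neighbours by the Leiden method at resolution 0.5, each library by itself, with seed 7. A cluster took the name of the cell type with the highest share of its markers raised at least 2-fold, after adding 10 CPM, and seen in at least 10% of the cells, with at least 3 such markers. The details of this rule were set after the counts had been seen. In the testis, Leydig transcripts reached every cluster, so a marker also had to exceed the median cluster of its own library. A cluster stayed unnamed when its median UMI count was over 3 times below the library's and none of its 10 top genes was a marker of its type, or when more of its 10 top genes marked another type. Counts of cells with a UMI were repeated after thinning every cell to 500 UMIs.

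The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The size rule and intervals were tested on simulated pairs of the cauda libraries over 26124 genes, 200 of them changed by a known fold. With all barcodes, 0 of 1099 unchanged genes at 100 CPM were past the rule, the interval covered the true fold for 95.5% of the unchanged genes, and the rule found 30 of 30 genes changed 8-fold, 32 of 32 changed 16-fold, 3 of 27 changed 4-fold and 0 of 13 changed 2-fold. With barcodes of at least 500 UMIs, 0 of 1121 unchanged genes passed, coverage was 94.7%, and the rule found 25 of 25 genes at 8-fold, 28 of 28 at 16-fold, 4 of 22 at 4-fold and 0 of 10 at 2-fold. Of 200 unchanged random lists in each, 3.5% and 5.5% lay outside the central 95%. On 600 simulated cells of 4 types over 26124 genes, 99.7% fell into a cluster of their own type and 15 of 18 doublets of mixed types were among the 30 barcodes removed. For the comparison of macrophages the rule itself is the same and no separate simulation was run.

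Alternatives were barcodes with at least 500 UMIs, CPM without mitochondrially encoded and ribosomal protein genes, scaling by the median of ratios, thinning the deeper side to the total of the shallower, 50 CPM, 2-fold, at least 1000 UMIs, at least 200 UMIs with 100 genes, a 10% mitochondrial limit, Leiden resolutions 0.3 and 1.0, and no doublet removal. Cell classes of the chimera and KO cauda were compared as an addition after the classes had been seen. A series-level list of barcodes with no counts of its own was not used here. Reads were not analysed here, so neither the genotype of single cells nor the deleted part of Tsc22d3 was called.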

Results

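Single-cell 3′ RNA counts were obtained from 3 mouse libraries, with no replicate animals. The chimera cauda library, labelled as spermatids and spermatozoa, held 5395856 UMIs over 214502 barcodes with at least 1 UMI, of which 222 reached at least 500 UMIs and carried 54.5% of the total. The KO cauda library, labelled as epididymal cells, held 41862286 UMIs in 3937 barcodes with a median of 8963 UMIs. The KO testis library held 134795047 UMIs in 18108 barcodes with a median of 4787.5 UMIs. Mitochondrially encoded genes took 12.2%, 9.33% and 16.4% of the UMIs in the chimera cauda, KO cauda and KO testis.

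Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659 on GRCm38), the gene knocked out in the host, encodes a glucocorticoid-induced leucine zipper protein needed for spermatogonial survival. Its level was 22.8 CPM (95% interval 18.9 to 27.2) in the chimera cauda, 10.8 CPM (9.85 to 11.9) in the KO cauda and 6.05 CPM (5.65 to 6.48) in the KO testis. In chimera barcodes with at least 500 UMIs it was 29.9 CPM (24.0 to 36.9). B lymphocyte-like cells of the chimera carried 4.0-fold (2.96 to 5.33) the level of those of the KO cauda, at 67.7 against 16.9 CPM, and macrophage-like cells 1.92-fold (1.18 to 3.02), at 13.0 against 6.78 CPM. In the KO testis the highest level of a named class was in spermatocyte-like cells, with 26.6 CPM (17.4 to 38.9). A 3′ tag outside the deleted part of the gene checks nothing, and the position of the deletion was not analysed here.

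Sperm transcripts separated the chimera cauda from the KO cauda. This comparison asks whether complementation with pluripotent stem cells brings germ cells to the cauda of a sterile knockout. Prm2 (ENSMUSG00000038015, chromosome 16, 10791380 to 10796134), a protamine that packs sperm DNA, stood at 3824 CPM in the chimera and 0.956 CPM in the KO cauda, a fold of 4002 (2938 to 5604). Odf1 (ENSMUSG00000061923, chromosome 15, 38219203 to 38226735), of the outer dense fibres of the sperm tail, was 4203-fold higher (2867 to 6436). Smcp (ENSMUSG00000074435, chromosome 3, 92583867 to 92588997), a protein of the sperm mitochondrial capsule, was 1433-fold higher (1175 to 1766). Among other genes with the largest folds, Tppp2 was 2818-fold (1292 to 7686), Osbp2 2411-fold (939 to 8862) and Ccdc136 2214-fold (947 to 6829.7) higher.

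The remaining named genes rested on 1 to 3 UMIs in the KO cauda, so their folds have wide intervals. Prm3 (ENSMUSG00000050058, chromosome 16, 10790505 to 10790914) had 701 UMIs in the chimera against 1, a ratio of 5439 (973 to 215113). Iqcf4 had 629 against 1, a ratio of 4879.9 (873 to 193049), and Fabp9, a fatty acid-binding protein of sperm, 605 against 1, a ratio of 4694 (839 to 185695). Spata18 had 1415 against 3 (1249.6 to 17766), Spz1 1057 against 3 (933 to 13276), Ubl4b 881 against 3 (777 to 11069) and Iqcf3 629 against 2 (673 to 20192).

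Of 1425 genes with at least 100 CPM in the higher library, 87 were past the size rule and higher in the chimera, and 0 were lower. The genes with the largest folds in the other direction stayed below 4-fold. Smc6, a subunit of a chromosome maintenance complex, was 2.93-fold higher (2.75 to 3.12) in the KO cauda. Ebf1, a transcription factor of B lymphocytes, followed at 2.32-fold (2.21 to 2.43), with the immunoglobulin light chain genes Iglc1 at 2.18-fold (2.09 to 2.27) and Iglc2 at 1.92-fold (1.86 to 1.99), the lymphotoxin gene Ltb at 2.30-fold (2.15 to 2.47), Ptprcap at 2.02-fold (1.85 to 2.22) and Cd180 at 1.99-fold (1.77 to 2.24). The others were Zbtb20 at 1.97-fold (1.85 to 2.09), Prtn3 at 2.30-fold (2.09 to 2.53), Gbp2b at 2.29-fold (2.07 to 2.56), Scd1 at 2.06-fold (1.90 to 2.24) and H2-Ea-ps at 2.01-fold (1.95 to 2.07).

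The 15 markers of elongating or condensed spermatids took 1.36% of the chimera UMIs (1.35 to 1.37), 0.000860% of the KO cauda UMIs and 0.000115% of the KO testis UMIs. The chimera share was 1585 times that of the KO cauda (1429 to 1763). Most of this signal lay outside cell-sized barcodes, since 65164 of the 73535 spermatid marker UMIs, 88.6% (88.4 to 88.8), were in barcodes with fewer than 500 UMIs. The 38774 barcodes with 20 to 49 UMIs alone held 35788 of them. Erythroid and epididymal principal cell markers also reached low barcodes, with 1.90% and 0.400% of the UMIs at 20 to 49 UMIs, where spermatid markers took 3.29%.

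**Figure D1:**
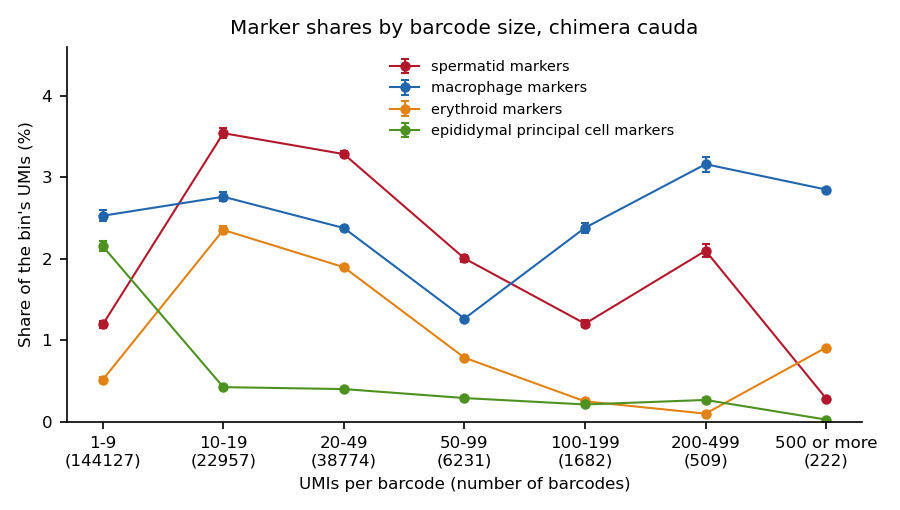
Share of UMIs in percent (vertical axis) taken by the markers of 4 cell types in chimera cauda barcodes grouped by UMIs per barcode (horizontal axis, number of barcodes in brackets); points are shares and bars exact binomial 95% intervals, often smaller than the points. Spermatid markers peaked at 3.54% in barcodes with 10 to 19 UMIs and took 0.285% in barcodes with at least 500 UMIs.

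With only chimera barcodes of at least 500 UMIs, where both cauda libraries share a lowest UMI count, spermatid markers took 0.285% of the UMIs, 331 times the KO cauda share (298 to 369). Then 31 of 1456 genes were past the size rule and higher in the chimera and 9 were lower. Odf1 was 861-fold (585 to 1322), Tppp2 842-fold (383 to 2309.5), Crisp2 728-fold (404 to 1467), Smcp 572-fold (468 to 706) and Dbil5 455-fold (319 to 674) higher. Prm2 was 319-fold (233 to 450.2), Oaz3 294-fold (211 to 421), Hspb9 236-fold (152 to 386), Akap12 123-fold (88.5 to 174) and Prm1 114-fold (85.6 to 154) higher. The globin genes Hba-a1 and Hba-a2 were 107-fold (101 to 114) and 76.4-fold (71.0 to 82.4) higher. The 9 lower genes included 3 of the epididymal secretion list. Crisp1 (ENSMUSG00000025431, chromosome 17, 40293758 to 40319207), which encodes a secreted protein that coats sperm in the epididymis, was 10.5-fold lower (9.69 to 11.3), Spink8 8.33-fold (7.02 to 9.96) and Wfdc10 7.17-fold (5.51 to 9.50). The other 6 were Spink10, Wfdc15b, Serpina1f, Cuzd1, Gpx3 and Defb28, from 10.1-fold to 4.69-fold lower. Over all barcodes Crisp1 differed by only 1.02-fold (1.01 to 1.04). Ptgds, Cd52 and Smc6 were 3.94-fold, 3.88-fold and 2.66-fold lower, below the size rule.

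Each of the germline lists stood higher in the chimera. All 7 measured genes of sperm chromatin compaction were higher, with a median log2 ratio of 9.28 (9.03 to 10.26), among them Prm1 at 1063-fold (814 to 1417), Tnp2 at 588-fold (427 to 832) and Tnp1 at 587-fold (409.9 to 872). All 16 measured flagellum genes were higher, with a median of 6.14 (5.47 to 6.54), and Odf2 was 11.1-fold (10.3 to 12) and Ropn1l 7.46-fold (5.77 to 9.62) higher, while Akap4 had 416 UMIs against 2 (444 to 13369). All 10 measured genes of sperm energy metabolism were higher, with a median of 6.78 (6.46 to 7.62), such as Gapdhs at 1646-fold (797 to 4101) and Pgk2 at 711-fold (373 to 1561), and Slc2a3 at 2.01-fold (1.59 to 2.53). Ion transport genes had a median of 3.35 (1.40 to 3.96) with 6 of 9 higher, led by Catsperg1 at 18.7-fold (13.5 to 26.2) and Catsperd at 10.2-fold (5.06 to 20.9), while the interval of the proton channel gene Hvcn1, at 0.912-fold (0.783 to 1.06), held 1. Acrosome genes had a median of 1.88 (1.33 to 2.96) with 9 of 11 higher, including Acrbp at 2.58-fold (2.0 to 3.29) and Zpbp at 2.47-fold (1.25 to 4.59), and Dkkl1 at 0.880-fold (0.684 to 1.12).

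Meiosis genes had a median log2 ratio of 5.08 (3.87 to 5.24) with 10 of 12 higher, among them the synaptonemal complex gene Syce2 at 36.8-fold (31.6 to 43.0) and the cohesin gene Stag3 at 11.1-fold (6.14 to 20.4). Pan-germline genes had a median of 2.48 (1.61 to 3.64) with 3 of 6 higher: Mael, with 54 UMIs against 0, was at least 139.6-fold higher, and Ddx4 and Piwil2 were 23.3-fold (8.85 to 71.6) and 7.05-fold (2.69 to 18.3) higher. These 7 lists lay at or above percentile 98.5 of random lists. In barcodes of at least 500 UMIs the medians were 6.83 for chromatin (7 of 7 higher), 4.83 for the flagellum (13 of 13), 5.31 for energy metabolism (10 of 10), 2.15 for ion transport (3 of 7), 1.37 for the acrosome (6 of 9), 3.44 for meiosis (6 of 10) and 2.65 for pan-germline genes (3 of 6). With the KO cauda thinned to the total of the chimera, the medians over all barcodes were 3.54 for the flagellum, 5.23 for energy metabolism and 2.21 (1.85 to 2.87) for meiosis. Among marker sets, spermatocyte markers had a median of 5.12 with 7 of 8 higher and round spermatid markers 4.37 with 8 of 9 higher. Most members of these sets are also in the meiosis, acrosome or ion transport lists, so their medians are not separate evidence. The spermatocyte markers summed to only 91 UMIs in the chimera against 10 in the KO cauda. Spermatogonium markers had a median of 0.22 (−0.04 to 1.71), with 3 of 7 higher.

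**Figure D2:**
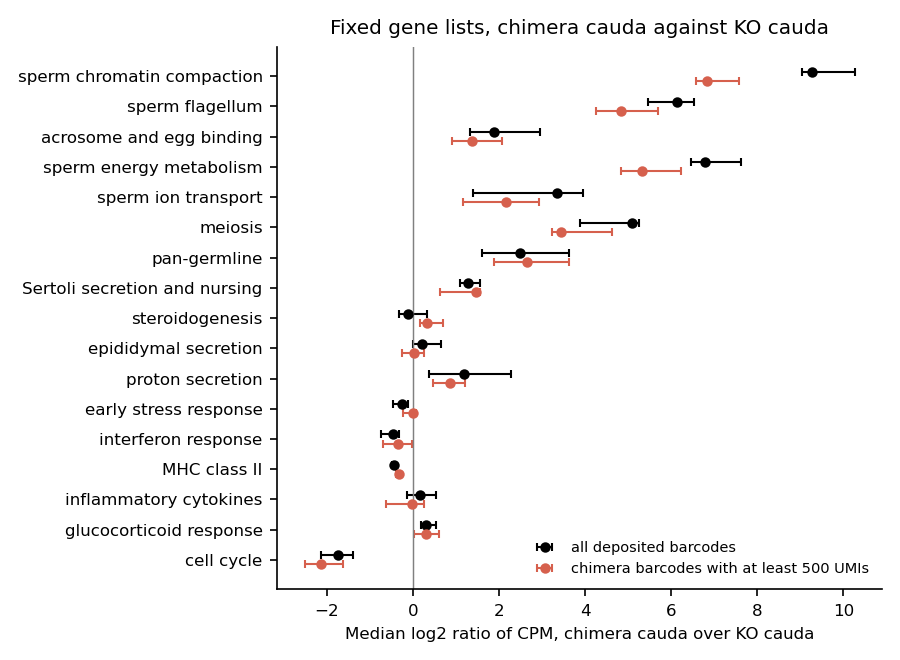
Median log2 ratio of CPM, chimera cauda over KO cauda (horizontal axis), for each fixed gene list (vertical axis), over all deposited barcodes (black) and over chimera barcodes with at least 500 UMIs (red); points are list medians and bars 95% intervals from Poisson redraws. Sperm chromatin compaction stood highest at 9.28 over all barcodes and 6.83 at 500 UMIs or more, and cell cycle lowest at −1.75 and −2.13.

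The lists outside the germline went in both directions. Cell cycle genes were lower in the chimera, with a median log2 ratio of −1.75 (−2.14 to −1.40) and 5 of 8 lower. Top2a stood at 0.257-fold (0.172 to 0.370) and Mki67 at 0.200-fold (0.113 to 0.327), while Pcna was 1.25-fold higher (1.11 to 1.41). Macrophage-like cells held 3498 of the 5247 KO cauda UMIs of this list, but their largest cluster, cluster 1, only 1162. KO cauda cluster 11, with 21 macrophage-like cells, had Top2a and Mki67 among its 10 top genes. The lower median therefore need not be a change across the library. Interferon response genes had a median of −0.45 (−0.74 to −0.31) with 6 of 10 lower and MHC class II genes −0.45 (−0.48 to −0.42) with 6 of 7 lower. Early stress genes had a median of −0.25 (−0.47 to −0.12) with 6 of 12 lower and 2 higher, but −0.00 (−0.23 to 0.07) with 4 lower and 1 higher in barcodes of at least 500 UMIs. Sertoli secretion genes had a median of 1.28 (1.09 to 1.56) with 4 of 6 higher, including transferrin (Trf) at 2.19-fold (2.14 to 2.25). Proton secretion genes had a median of 1.19 (0.37 to 2.27) with 3 of 8 higher, such as Car2 at 21.2-fold (17.6 to 25.7). Glucocorticoid response genes had a median of 0.29 (0.18 to 0.54) with 4 of 7 higher and 1 lower. Inflammatory cytokine genes, at 0.17 (−0.14 to 0.54) with 2 of 11 higher and 2 lower, steroidogenesis genes, at −0.12 (−0.32 to 0.33) with 2 of 10 higher, and epididymal secretion genes, at 0.21 (−0.00 to 0.66) with 3 of 14 higher and 1 lower, had intervals of the median that held 0, the last one narrowly, since another set of redraws gave 0.00 to 0.60. In barcodes of at least 500 UMIs the medians were −2.13 for cell cycle (5 of 8 lower, 1 higher), −0.35 for interferon response (3 of 10 lower), −0.32 for MHC class II (5 of 7 lower) and 1.48 for Sertoli secretion genes (2 of 6 higher). They were 0.30 for glucocorticoid response (3 of 7 higher, 1 lower), −0.01 for inflammatory cytokine (2 of 11 higher, 3 lower) and 0.33 for steroidogenesis genes (2 of 10 higher, 1 lower). For proton secretion the median of 0.86 went with 2 of 8 higher and 3 lower, and with 17.0 against 20.9 CPM in sum. For epididymal secretion the median of 0.02 went with 1 of 14 higher and 6 lower, and with 353 against 3043 CPM in sum.

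Markers of other cell types also differed between the cauda libraries. Erythroid markers were higher in the chimera, with a median log2 ratio of 6.48 and 5 of 5 higher, for example Hbb-bs at 78.5-fold (75.5 to 81.5). Fibroblast markers were higher over all barcodes, with a median of 3.19 and 5 of 6 members, such as Col1a1 at 18.5-fold (10.9 to 32.4). In barcodes of at least 500 UMIs the summed excess was gone, with a median of 1.47, 2 of 5 higher and 1 lower, and 18.4 against 20 CPM in sum. T or NK lymphocyte markers stood at −1.84 with 5 of 7 lower, B lymphocyte markers at −0.62 with 5 of 6 lower, monocyte markers at −0.56 with 3 of 5 lower, and macrophage markers at 0.30 with 7 of 10 higher and 2 lower. In barcodes of at least 500 UMIs the medians were 5.95 for erythroid (5 of 5 higher), −3.06 for T or NK lymphocyte (5 of 7 lower), −0.55 for B lymphocyte (6 of 6 lower), −0.71 for monocyte (4 of 5 lower, 1 higher) and 0.40 for macrophage markers (7 of 10 higher, 2 lower). Mast cell markers stood at 1.13 over all barcodes with 4 of 5 higher and at −4.58 in barcodes of at least 500 UMIs with 4 of 5 lower. General epithelial markers stood at −0.24 and −2.64, with 2 and then 6 of 6 lower. Over all barcodes, epididymal markers had medians of 0.37 for principal cells with 3 of 7 higher, 1.19 for clear or narrow cells with 2 of 6 higher and −0.54 for basal cells with 1 of 6 lower. Sparse sets, also over all barcodes, had medians of 2.32 for Sertoli cells with 3 of 5 higher, 1.18 for smooth muscle with 1 of 6 higher, 0.88 for lymphatic endothelium with 1 of 3 higher, 0.63 for neutrophils with 2 of 4 higher and 1 lower (85.4 against 111.7 CPM in sum), and −0.02 for dendritic cells with 1 of 6 lower. They were −0.27 for pericytes with 1 of 2 lower, −0.35 for endothelium with 1 of 4 lower, −0.44 for Leydig cells with 1 of 7 lower, −0.83 for mesothelium with 2 of 4 lower, and −0.04 for Schwann cells with the 1 measured member holding 1.

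After the barcode filter, 184 chimera barcodes formed 4 clusters with a median of 13292.5 UMIs, and 3426 KO cauda barcodes formed 11 clusters with a median of 9441.5 UMIs. A spermatid-like cluster of 26 chimera barcodes made up 14.1% (9.44 to 20) of the kept barcodes, with a median of 1239.5 UMIs. This share was 27.3%, 42 of 154 barcodes, with at least 1000 UMIs and 31.0%, 53 of 171, with a mitochondrial limit of 10%. These filters keep fewer barcodes, so others than the 26 took the name when barcodes were grouped again. Cluster 3 of the chimera, 45 barcodes with a median of 1177 UMIs, stayed unnamed, and its 10 top genes included Spink8 and Defb28 of the epididymis and Ldhc and Catsperz of the germline. No KO cauda cluster was germ cell-like. With every cell thinned to 500 UMIs, Smcp was seen in 26 of 26 spermatid-like cells against 2 of 59 macrophage-like and 2 of 54 B lymphocyte-like cells, classes with median depths of 1239.5, 30319 and 13488 UMIs that should lack it. Without thinning it was seen in 41 of 59 macrophage-like and 31 of 54 B lymphocyte-like cells. Prm2 was seen in 16 of 26 spermatid-like cells after thinning, against 0 of 59 and 2 of 54.

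Leukocyte-like classes made up most of the kept barcodes of both cauda libraries; the filter leaves out the low barcodes that held most spermatid UMIs. Macrophage-like cells were 32.1% (25.4 to 39.3) of the chimera cauda, all in cluster 1, and 30.5% (29.0 to 32.1) of the KO cauda, where cluster 1 held 987 of the 1045 cells. B lymphocyte-like cells were 29.3% (22.9 to 36.5) of the chimera cauda, in cluster 2, and 48.5% (46.8 to 50.1) of the KO cauda, with 790, 663 and 207 of 1660 cells in clusters 2, 3 and 5. T or NK lymphocyte-like cells were 3.62% (3.02 to 4.30) of the KO cauda and formed no cluster of their own in the chimera, which does not count single cells within other clusters. Clusters left unnamed held 24.5% of the chimera cauda, 17.4% of the KO cauda and 10.7% of the KO testis. In the KO cauda these were clusters 4 and 6, led by epithelial markers at low UMI counts, with 7.06% and 5.20% of the cells, and cluster 7, with B lymphocyte markers and Ccr7, with 5.17%. At Leiden resolution 1.0 the B lymphocyte share of the KO cauda was 25.5%.

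**Figure D3:**
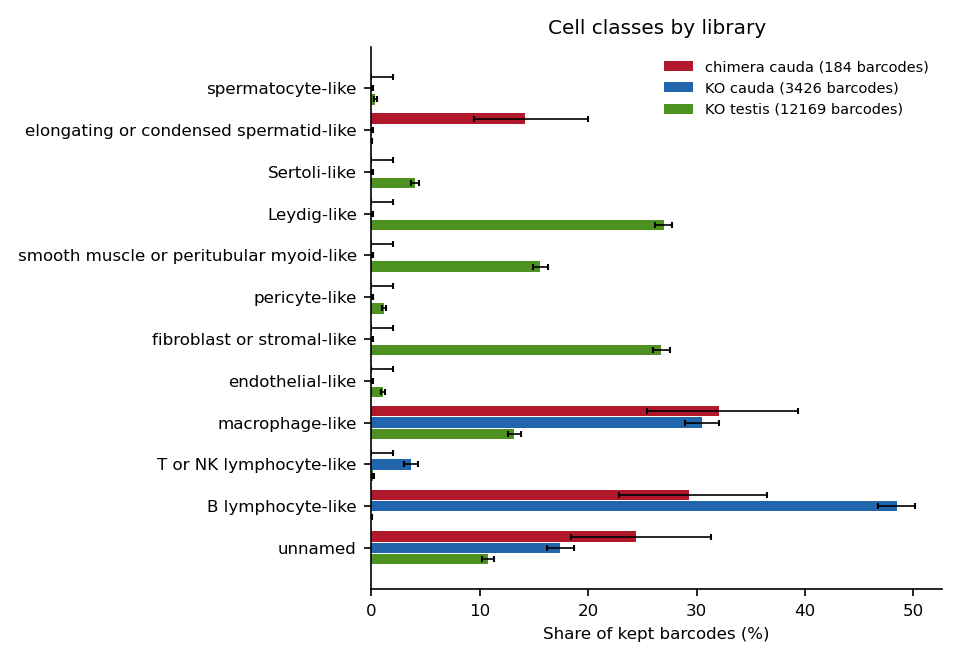
Share of kept barcodes in percent (horizontal axis, from 0) in each cell class (vertical axis) for the chimera cauda, KO cauda and KO testis; bars are shares and whiskers exact binomial 95% intervals. Spermatid-like barcodes made up 14.1% of the chimera cauda, no cluster of the KO cauda or KO testis had this name, and Leydig-like cells led the KO testis with 27.0%.

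The named cells of the KO testis were somatic, apart from a small germ cell-like cluster. This library shows what the sterile host testis contained. Of 12169 kept barcodes in 18 clusters, 27.0% (26.2 to 27.8) were Leydig-like, 26.8% (26.0 to 27.6) fibroblast-like, 15.6% (15 to 16.3) smooth muscle-like or peritubular myoid-like, 13.2% (12.6 to 13.8) macrophage-like and 4.0% (3.66 to 4.37) Sertoli-like. Pericyte-like, endothelial-like and T or NK lymphocyte-like cells were 1.13%, 1.05% and 0.189%. A spermatocyte-like cluster held 45 barcodes, 0.370% (0.27 to 0.495), at a median of 19842 UMIs. It raised 8 of 9 spermatocyte markers but also 7 of 10 spermatogonium markers, so its name does not fix the germ cell stage. Stra8, on the spermatogonium list, was seen in 42 of its cells, or in 5 after thinning to 500 UMIs. After thinning to 500 UMIs, Dazl, an RNA-binding protein of germ cells, was seen in 22 of these 45 cells, against 9 of 487 Sertoli-like and 0 of 3280 Leydig-like cells with median depths of 14479 and 15235 UMIs, and Sycp3 of the synaptonemal complex in 14 of 45 against 1 of 487 and 0 of 3280. Prm1 and Prm2 were seen in 0 of these 45 cells. Without a mitochondrial limit, Leydig-like cells were 44.4% of the testis, since 3254 of 6861 of them, 47.4% (46.2 to 48.6), exceeded 20% mitochondrial UMIs. With a limit of 10% their share was 13.5% and the germ cell-like share 0.983%.

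Macrophage-like cells of the KO cauda and KO testis differed in many genes. The comparison sets this class in the cauda aspirate beside that in the dissociated testis, so tissue and preparation differ together. In the cauda, Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), which encodes the lubricating glycoprotein lubricin, reached 6270.4 CPM and was 561-fold higher (465 to 684). The lipoxygenase gene Alox15 was 675-fold (483 to 975), the acute-phase gene Saa3 469.6-fold (352 to 642), and the coagulation factor genes F10 and F5 956-fold (439 to 2605) and 462-fold (308 to 728) higher. Prtn3 was 577-fold (279.8 to 1435) and Padi4 555-fold (217 to 2038) higher, while Serpinb10 (165 to 4932) and Pi16 (149.6 to 4471) rested on 2 UMIs each in the testis. Crisp1, with 22903 UMIs against 0, was at least 4003-fold higher, but its 1243 CPM in these cells lay below the 2385 CPM of the whole KO cauda library.

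In the testis, Slc40a1 (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), the iron exporter ferroportin, had 7901 UMIs against 3, a ratio of 5023 (1718 to 24362). The chemokine genes Ccl7, with 4580 against 2 (1208 to 36075), Ccl12, with 3020 against 2 (797 to 23791), and Ccl8, 1728-fold higher (965 to 3463), and the lectin genes Cd209f, at least 2394-fold higher, and Cd209g, with 1378 against 2 (363 to 10862), stood beside it. Slco2b1 (549 to 16413) rested on 2 and Defb19 (699 to 9919) on 3 cauda UMIs. The Leydig cell genes Insl3 (334 to 10003) and Hsd3b1 (299 to 8964) also ranked here. Of 1726 genes, 108 were past the size rule and higher in the cauda and 183 higher in the testis, from 1045 and 1605 cells. Of those, 11 (10.2%) and 27 (14.8%) had a lower level in the macrophage-like class than in their whole library. The macrophage markers themselves had a median log2 ratio of −1.28, with 8 of 10 lower and 2 higher in the cauda. Lyz2 was 3.02-fold (3.0 to 3.04) higher in the cauda, whereas Mrc1 stood at 15.5 CPM in the cauda and 1766 CPM in the testis and Cx3cr1 at 5.10 and 1605 CPM.

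**Figure D4:**
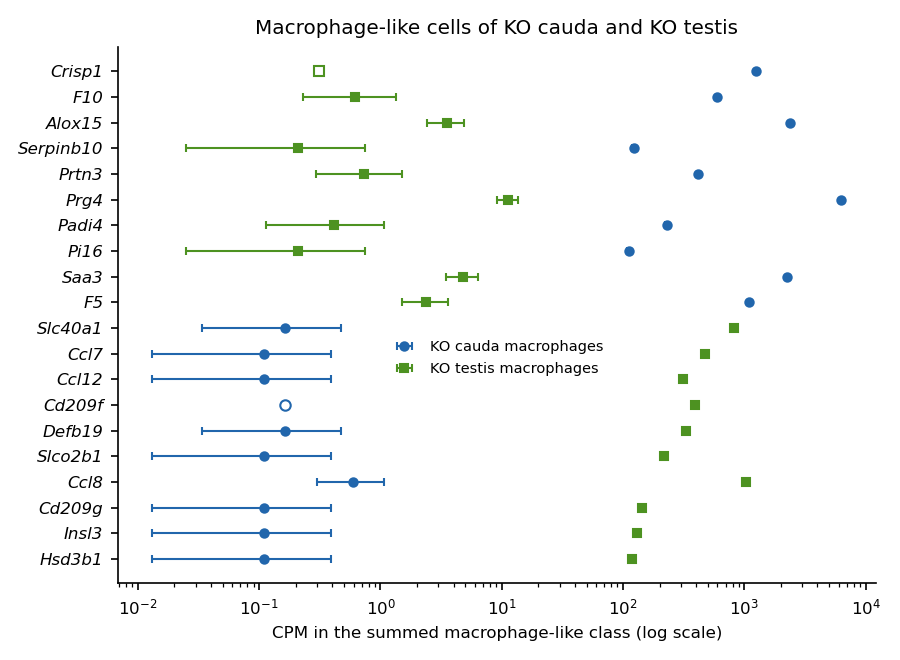
CPM on a log scale (horizontal axis) of the 20 genes with the largest folds (vertical axis) in macrophage-like cells of the KO cauda (circles) and KO testis (squares); bars are exact Poisson 95% intervals, and open symbols mark 0 UMIs drawn at the floor of 3 UMIs. Prg4 stood at 6270.4 CPM in the cauda and 11.2 CPM in the testis, and Slc40a1 at 0.163 and 818 CPM.

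Early stress genes were lower in cauda macrophages for 12 of 12 members, with a median log2 ratio of −3.61 (−3.77 to −3.48): Fos was 248-fold (221 to 279.8), Jun 92.4-fold (86.3 to 99) and Egr1 34.8-fold (32.6 to 37.2) higher in the testis. Inflammatory cytokine genes stood at −4.12 (−4.55 to −3.69) with 9 of 11 lower and 1 higher, for example Ccl2, 348-fold (276 to 446) higher in the testis, and Ccl4, 67.4-fold (57.6 to 79.3). Glucocorticoid response genes stood at −1.23 (−1.36 to −1.02) with 5 of 7 lower and 2 higher, led by Dusp1, 16-fold higher (15.3 to 16.8) in the testis. Interferon response genes stood at 0.15 (−0.05 to 0.31) with 5 of 10 higher and 5 lower. Over the whole libraries, early stress genes summed to 10673 CPM in the KO testis and 707 CPM in the KO cauda. Inflammatory cytokine genes summed to 801 and 202 CPM. The testis was dissociated and the cauda aspirated, so preparation cannot be told apart from tissue in these differences. The steroidogenesis list, at −7.21, and the Leydig markers, at −8.90 with 8 of 8 lower, were lower in the cauda, and the epididymal secretion list, at 2.72 with 6 of 10 higher and 3 lower, was higher.

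MHC class II and cell cycle results depended on which clusters were counted as macrophages. MHC class II genes were higher in the cauda with a median log2 ratio of 2.61 (2.27 to 2.65) and 6 of 7 members, such as Cd74 at 6.14-fold (5.87 to 6.42). Markers of other immune cells moved with them, with medians of 4.41 for B lymphocytes (5 of 6 higher, 1 lower), 2.24 for dendritic cells (4 of 6 higher, 1 lower) and 1.65 for monocytes (5 of 5 higher). In sum, however, the B lymphocyte markers were lower in the cauda, at 139 against 350 CPM. With the largest cluster of each library alone the median was 1.05, and it was −0.40 after adding testis clusters 8 and 14, which showed all 10 macrophage markers, held 3.20% and 1.08% of the testis cells and had stayed unnamed. Cell cycle genes stood at 1.67 (1.33 to 1.90) with 6 of 8 higher and 1 lower, led by Ube2c at 33.6-fold (16.9 to 78.3), and at −1.43 with the largest clusters alone. Without doublet removal the medians were 0.44 for MHC class II and −3.21 for cell cycle genes.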

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

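The alternatives without a mitochondrial limit, with other clusters in the macrophage class, and for the chimera against KO cell classes were chosen after the results were seen. Scaling moved the median gene of the cauda comparison by −0.17 (log2) without mitochondrially encoded and ribosomal protein genes, by −0.16 with the median of ratios and by 0.16 with barcodes of at least 500 UMIs. Beside the values below, 15 of 24 recomputed main counts of genes, 14 of 21 germline list medians and 20 of 42 shares and levels stayed within their bounds, as did 26 of 30 other list medians and 2 of 10 other counts. A further 5 shares and levels are not counted, since their alternative uses the same barcodes: KO barcodes all reach 500 UMIs, and no chimera doublet was removed. Of 72 recomputed folds of named genes of the cauda comparison, 37 moved beyond their intervals and none changed direction. Since these genes were named for having the largest folds, the kept direction says little about other genes.

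With only barcodes of at least 500 UMIs, cauda genes past the size rule came to 31 higher and 9 lower in the chimera, median log2 ratios to 6.83 for chromatin compaction, 4.83 for the flagellum, 5.31 for energy metabolism and 3.44 for meiosis, the spermatid marker share to 0.285% and Tsc22d3 to 29.9 CPM. By construction this leaves out the low barcodes that held most spermatid UMIs. Without mitochondrially encoded and ribosomal protein genes 1 gene was lower in the chimera, the spermatid marker shares were 1.92%, 0.00137% and 0.000159% in the chimera cauda, KO cauda and KO testis, and Tsc22d3 stood at 32.2, 17.2 and 8.37 CPM, from the smaller total alone. Thinning the KO cauda gave 3.54 for the flagellum, 5.23 for energy metabolism and 2.21 for meiosis, since members at low counts drop to the floor. At 50 CPM, 143 genes were higher and 2 lower, and with a minimum fold of 2, 148 and 12, as looser rules admit more genes.

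The germ cell-like share of the chimera was 27.3% at 1000 UMIs and 31.0% at a 10% mitochondrial limit. That of the KO testis was 0.647% at 1000 UMIs, 0.983% at the 10% limit, 0.194% without a limit and 0.695% without doublet removal. The Leydig-like share was 28.6% at 1000 UMIs, 13.5% at the 10% limit and 44.4% without a limit. The B lymphocyte-like share of the KO cauda was 45.0% at 1000 UMIs, 53.5% at 200 UMIs with 100 genes, 38.5% at the 10% limit, 43.6% without a limit and 25.5% at Leiden resolution 1.0. No KO cauda barcode holds under 501 UMIs, so the setting of 200 UMIs with 100 genes could add at most 37 barcodes with few genes. These are too few to give 53.5% unless barcodes were grouped or named anew. A stricter mitochondrial limit removes Leydig-like cells above others, 47.4% of them at 20%. For the remaining shares the cause was not tested. At 50 CPM, 166 genes were higher in cauda and 282 in testis macrophages. No paired analysis was possible because each group holds 1 library, and no result comes from a test. The depth of the chimera, 5395856 UMIs, sets a floor of 0.556 CPM, so genes below it in the KO libraries cannot be called lower in the chimera.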

Other observations

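The comparisons of cell classes between the chimera and KO cauda, the Cell Ranger, B cell mix, T or NK lymphocyte, low-Ly6a cell, free RNA and barcode filter tests, and the split of sperm genes within barcodes were chosen after the results they bear on had been seen; the co-occurrence, mt-Rnr2 and peritoneal gene tests and the tests of H2-Ea-ps and Tsc22d3 by Ly6a were written before. Macrophage-like cells of the chimera (59 cells) carried less MHC class II than those of the KO cauda (1045 cells), with 7 of 7 genes lower and a median log2 ratio of −3.42 (−3.96 to −3.25). The invariant chain gene Cd74 was 15.6-fold lower (13.3 to 18.4), H2-Aa 15.3-fold (12 to 19.8), H2-Eb1 10.7-fold and H2-Ab1 10.6-fold. With KO cluster 1 alone the median was −2.18, and Cd74 was 6.88-fold, H2-Aa 5.63-fold and H2-Ab1 4.53-fold lower, while H2-Eb1, 3.12-fold lower, was no longer past the size rule. Retnla was 28.3-fold lower (19.6 to 42.6), or 15.7-fold against cluster 1 alone, and Cd52 20-fold (15 to 27.1), or 18.2-fold. H2-Ea-ps was 30.1-fold lower (20.1 to 47.6), or 12.1-fold. Summed MHC class II genes stood at 291 CPM in chimera macrophages and 2909 CPM in KO cauda macrophages (1280 CPM in cluster 1). Their whole libraries stood higher, at 7514 and 10525 CPM, so free RNA of other cells cannot be told apart from a change within macrophages. Cd52 also stood lower in the KO class than in its library, at 543 against 1762 CPM. Other sets moved too: monocyte markers stood at −1.59 with 4 of 5 lower, cell cycle genes at −2.94 with 6 of 8 lower (−0.00 with cluster 1 alone), spermatid markers at 6.71 with 8 of 9 higher and erythroid markers at 3.68 with 4 of 4 higher, and Crisp1 was 10.3-fold lower. The actin-bundling gene Fscn1 was 5.90-fold (5.06 to 6.87) and the apolipoprotein gene Apoc1 4.32-fold (3.80 to 4.90) higher. Of 1507 genes, 4 were past the size rule and higher in the chimera and 9 were lower.

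B lymphocyte-like cells of the chimera (54 cells) differed from those of the KO cauda (1660 cells) mainly in Ly6 genes, which encode small surface proteins. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031 on GRCm38) stood at 711 against 13.2 CPM, 53.7-fold higher (45.9 to 63.0), Ly6d was 9.28-fold (8.50 to 10.1) and Ly6e 8.89-fold (8.26 to 9.57) higher, and the antiviral deaminase gene Apobec3 was 11.8-fold higher (10.3 to 13.5). Of 1237 genes, 11 were higher and 4 lower, the lower ones including the epididymal genes Gpx3 (10.7 to 152), which rested on 3 chimera UMIs, Crisp1 at 21.4-fold (16.4 to 28.4) and Spink8 at 12.5-fold (6.05 to 31.1). Spermatid markers stood at 6.57 with 6 of 7 higher and erythroid markers at 3.0 with 4 of 4 higher. The T or NK lymphocyte markers also stood higher in this chimera cluster, with a median log2 ratio of 1.77 (1.42 to 3.25) and 66.5 against 18.1 CPM in sum, through Nkg7 (29 UMIs) and Klrd1 (15 UMIs), each seen in 1 cell. Nme2, Grcc10 and Erh were higher in both classes, by 5.60-fold, 5.23-fold and 4.24-fold in B lymphocyte-like and 3.94-fold, 3.74-fold and 2.71-fold in macrophage-like cells.

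Sperm transcripts in the chimera cauda lay mostly in barcodes with few UMIs. The barcodes under 500 UMIs that only the chimera matrix kept held 88.6% of the spermatid marker UMIs but are not the whole cause of the difference, since the fold over the KO cauda fell from 1585 to 331 (298 to 369) without them. Free RNA alone, a shared pool with its genes in 1 ratio, is argued against by the split between chromatin and tail or energy genes. In barcodes with at least 50 and under 200 UMIs its variance was 2.0 times binomial (0.947 to 1.06 in simulated draws). The variance rose from 1.23 at 10 to 19 UMIs to 11.7 from 200 to under 500. At 20 to 49 UMIs it was 1.33 (0.979 to 1.02 in simulated draws). Those barcodes held 18338 chromatin and 16676 tail or energy UMIs, against 4580 and 6018 from 50 to under 200. The excess was thus small where more of these UMIs lay. The split test replaced a first test, the variance of the total spermatid count (6.30 times binomial, 8.84 for erythroid markers), which does not separate a pool from cells. The co-occurrence test written in advance did not argue against free RNA, with both gene groups together in 0.669 of the barcodes expected by chance, where 1.1 or less had been set for free RNA and pairings with macrophage markers gave 0.587. That sperm mitochondria bring the mt-Rnr2 of these barcodes remains open: barcodes rich in mt-Rnr2 held 3.72 times (3.58 to 3.87) the spermatid share, as that explanation had set, but erythroid markers, added afterwards as a control, gave 5.69, and intact sperm with little RNA, sperm fragments and free RNA beside them may all contribute.

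The Ly6 and H2-Ea-ps differences between chimera and KO cells concern genes known to vary between mouse strains. H2-Ea-ps, however, was only 1.37-fold lower in chimera B lymphocyte-like cells. Its 30.1-fold lower level in macrophage-like cells came together with lower MHC class II genes, so it is no separate sign of a strain difference. A change of Cell Ranger version alone is argued against for Ly6e, since a change of software moves a gene alike in all cells. The Ly6e fold differed by 14.6 times between B lymphocyte-like (8.89) and macrophage-like cells (0.611), or by 14.5 times against KO macrophage cluster 1 alone. The H2-Ea-ps folds differed by 22.0 times, or by 8.85 times against cluster 1 alone. That gap came with the lower MHC class II genes of chimera macrophages, so it says little about software. Another mix of the B cells found in the KO cauda is argued against for Ly6a. Its highest level in any KO cauda cluster was 27.1 CPM (15.2 to 44.8), against 711 CPM in chimera B lymphocyte-like cells. This does not cover Ly6d, among the 10 top genes of KO cauda clusters 3 and 7, or B cells of a type absent from the KO cauda. T or NK lymphocytes within the chimera cluster are also argued against. Without cells holding a UMI of their markers, Ly6a was still 46.5-fold (39.5 to 54.9) and Ly6d, Ly6e and Apobec3 9.15-fold, 8.39-fold and 11-fold higher. That the 16 chimera B cells with fewer than 3 Ly6a UMIs are as a group of the KO type is argued against, since they carried 7.91 times (6.58 to 9.44) the Ly6e, 11.9 times (8.71 to 15.9) the Apobec3 and 10.7 times (8.78 to 12.8) the Ly6d of KO cells, but a mixture of genotypes that Ly6a does not mark, or a few KO-type cells, cannot be told apart from 1 genotype: 84.2% (68.7 to 94.0) of the 38 cells with at least 3 Ly6a UMIs and 68.8% (41.3 to 89.0) of the 16 others had an H2-Ea-ps UMI, at median depths of 17466 and 7538.5 UMIs, and Tsc22d3 stood at 0.872 times (0.424 to 2.02) the level of the others. A donor or host strain difference, which the iPSC complementation allows, remains open as untested.

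Macrophages of the KO cauda and the KO testis differ in 291 genes past the size rule. Free RNA of each tissue is argued against as the whole cause, since only 13.1% of these genes had a lower level in the class than in its library, although this share includes Crisp1, Insl3 and Hsd3b1. Peritoneal-type macrophages in the cauda aspirate are a candidate explanation: 7 of 7 further genes of large peritoneal macrophages, set before they were looked at and in no other list, were higher in the cauda, with a median log2 ratio of 7.04 (6.07 to 8.10), among them Icam2 at 685 against 1.86 CPM, Selp at 507 against 1.55 CPM and Gata6 at 145 against 0.725 CPM, while Timd4 and Vsig4 reached 97.9 and 123 CPM in the testis too. The chimera macrophages showed the same genes at 7.70 over the testis. Residence in another tissue, which the labels name, remains open as untested. It cannot be told apart from the preparation, since the testis was dissociated and the cauda aspirated. No sort or gate on cell type is named in the labels.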
